A study of Oryza sativa with 2 samples.

How the data were processed

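RNA from rice leaves was measured on 2 single-colour oligonucleotide arrays, 1 for plants with yellow leaf tips and 1 for green plants. Both were recombinant inbred lines, that is, lines fixed by inbreeding from a cross. Per the labels' protocols, total RNA was isolated with the RNeasy plant mini kit, and about 10 µg of it was turned into biotinylated cRNA. Whether each RNA came from 1 plant, several plants or several lines is not given in the sources used here.

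The deposited values are signal intensity on a linear scale, 1 per probe set and array, for 57381 probe sets. The software and the scaling behind them are not given in the sources used here. The deposited intensity values gave a mean of 500.1 on each array after the lowest and highest 2% were left out, so both arrays had the same overall level before any step described below. The median of the rice probe sets was 80.5 on the yellow leaf tip array and 97.5 on the green array. No value was below 0 on either array.

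The 123 control probe sets were left out of the comparison, which left 57258. A pseudocount of 22.6, the 25th percentile of all values of both arrays, was added before taking log2. Probe sets were kept where the mean of both arrays was at or above the median of those means, 86.0, which left 28629. The log2 difference, yellow leaf tip minus green, was centred on its median over the kept probe sets, a shift of -0.05. Folds in the text are on the scale of log2 of value plus pseudocount and understate the difference of dim genes. A probe set was counted as higher or lower where this centred difference was at least 1 in size, that is, a fold of 2. With 1 array per group there was no test, and a count describes these arrays.

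Of the probe sets, 22436 had 1 gene in the platform annotation, 95 had several and 34727 rice probe sets had none listed. All 17905 single genes were found by gene identifier in the RefSeq gene table of assembly ASM3414082v1, which was used for names and for the order of neighbouring genes only. The value of a gene was the mean over its kept probe sets, for 14697 genes, of which 2050 had a name other than a locus number. The spread between probe sets of the same gene was the pooled SD of their differences, over 2215 genes with several kept probe sets. It covers disagreement between probes, not plants, RNA extractions or arrays. The number of arrays limits the precision.

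The measures, thresholds, filter, alternatives, topics of the gene lists and the rule for named genes were fixed before the data were examined. The tests of explanations near the end were not part of this plan, and when they were chosen is stated there. The planned membership of the lists, by locus identifier or gene description, could not be applied: 0 of the 169 planned identifiers matched the gene table, and it holds no descriptions. Members were therefore matched by gene symbol and synonym for 30 of the planned topics, with 10 symbol families added. These symbol patterns were written after the annotation was seen and before the values of named genes. The added families were heat shock factors, phosphate supply, sugar transport and cleavage, auxin response, cytokinin response regulators and metallothioneins. Calcium sensors and kinases, protein phosphatases 2C, germin-like proteins, and starch synthesis and amylases were added too. The planned lists of plastid ribosomal proteins and retrotransposons had no usable symbols and were not analysed here, and a list of chitin and pattern receptors took the place of disease resistance receptors. A few members whose symbols matched by accident were taken out after a first look at the values, so the lists were also run with them. For each list with at least 3 measured genes, the median difference was placed among 10000 random lists of the same size, drawn from the kept genes in the same decile of signal level.

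The genes named in the text are the 12 highest and 12 lowest kept genes with a name, up to 2 highest and 2 lowest members of each list, and 20 genes chosen in advance, whatever their values. The plan asked for a gene description and here a name stood in for it. Transposon genes were not named. Of the 20 genes, 13 were measured under their name, and NYC3, PAO, NAP, PR1a, PR1b, WRKY45 and CATC were not analysed here under those names. Where the probe sets of a named gene differed by more than 1 on the log2 scale, the text says so.

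Alternatives were no centring, quantile normalization, a loess of the difference on the signal level (fraction 0.3), no pseudocount, a pseudocount at the 50th percentile, no filter, a filter at the 75th percentile, leaving out probe sets whose names mark possible cross-hybridization, the brightest probe set per gene, and a size threshold of 2. Chosen after seeing the data were random lists drawn from named genes only, lists with the removed members, the gene listed as CAO counted among chlorophyll breakdown genes, and counts without probe sets whose names begin with OsAffx.

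The calculation was tested on simulated data. Both simulated arrays were drawn from the green array with noise of the size of the spread between probe sets, and 200 probe sets were altered. Of the 4-fold alterations 100% passed the threshold, and of the 2-fold alterations, which sit at the threshold after the pseudocount has shrunk them, 37.0% did. Of 28450 unaltered probe sets, 1.81% passed it. The noise was set by the pooled spread, whereas the spread in the real data depended on signal. It was 0.85 in the dimmest band of kept probe sets and 0.22 in the brightest. The noise also left out differences between plants, RNA extractions and arrays. These shares therefore hold for the simulated noise only, and 1.81% is no estimate of false calls on the real arrays. Of 40 random lists of 15 unaltered genes, 3 fell outside the central 95% of random lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.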

Results

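Transcript levels were compared between leaves of rice recombinant inbred lines whose leaf tips turned yellow in the vegetative stage and leaves of lines that stayed green. The title of the first sample says yellow leaves and its description says yellow leaf tip, so these labels do not settle which part was taken. The series concerns SA0420, an early-senescing rice mutant, and the comparison was made to follow the molecular events of leaf-tip yellowing. Each group had 1 array and there were no replicates, so the differences below compare these arrays, not the conditions. Across the kept probe sets the log2 signals of both arrays correlated with r = 0.93, a correlation across probe sets, which are not independent replicates.

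The leaves with yellow tips had much higher signals for SGR, which promotes chlorophyll breakdown, for the sugar transporter SWEET15 and for genes of the glyoxylate cycle. They had lower signals for a list of carbon fixation and photorespiration genes, most of them of photorespiration, and for PORA of chlorophyll synthesis. Of 28629 kept probe sets, 1665 (5.82%) were higher in yellow leaf tips by at least 2-fold and 1800 (6.29%) were lower. The higher share of these calls was 48.1%, and it was 42.8% without centring and 59.4% when the difference was first levelled by loess on signal. At a log2 difference of 2, the counts were 312 higher and 261 lower. At the level of single genes, 819 were higher and 468 lower, and among genes with a name 133 were higher and 76 lower.

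The spread between probe sets of the same gene was 0.46 (SD of the log2 difference, 2215 genes), and it depended on signal. It was 0.85 in the dimmest 20% of the kept probe sets and 0.22 in the brightest 20%. In the dimmest 20%, lower calls outnumbered higher ones, 1014 against 524, while in the brightest 20% 207 probe sets were higher and 109 lower. Names were sparse at the extremes: 13 of the 100 highest and 2 of the 100 lowest probe sets belonged to a named gene.

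**Figure D1:**
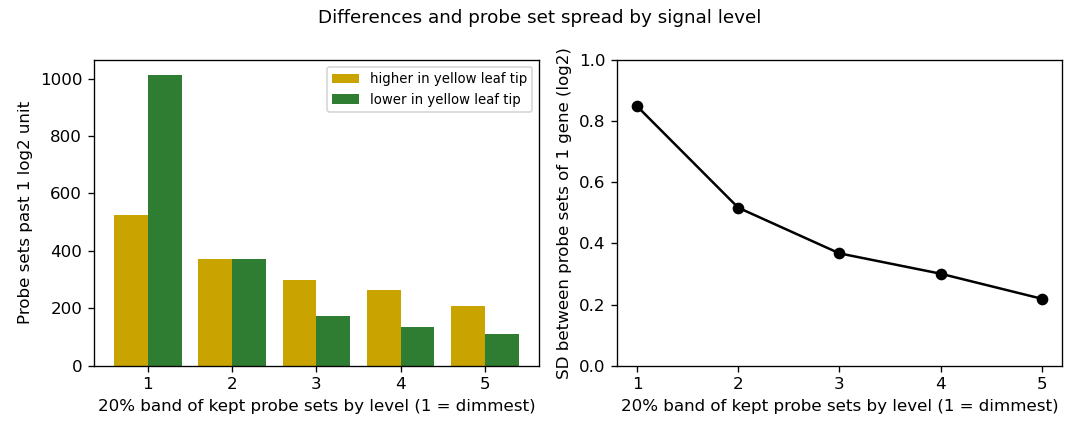
Left, the number of kept probe sets higher (yellow bars) or lower (green bars) in yellow leaf tips by at least 1 log2 unit, for each 20% band of the signal level; right, the SD of the log2 difference between probe sets of the same gene in each band. Lower calls prevail in the dimmest band (1014 against 524), where the SD is 0.85, and higher calls in the brightest band (207 against 109), where it is 0.22.

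The highest named gene was SWEET15, which encodes a sugar efflux transporter, with a signal of 4291 in yellow leaf tips and 139 in green leaves, a fold of 27.7. EGY3, related to chloroplast membrane proteases, had 3308 against 147 (20.3-fold). PXG, a peroxygenase gene, had 3463 against 301 (11.2-fold), and the chitinase gene Cht4 had 581 against 45.2 (9.23-fold). The dehydrin gene RAB16B and the late embryogenesis abundant gene LEA19 had signals of 257 and 205 in yellow leaf tips, and in green leaves 9.24 and 5.84, both below the pseudocount. The size of their differences therefore depended on the settings, from 1.86 to 4.85 for RAB16B and from 1.68 to 5.19 for LEA19. LEA19 was read only by a probe set that may cross-hybridize. The sugar transporter SWEET2b had a log2 difference of 2.98, on 2 probe sets that differed by 0.08. The homeodomain gene HOX22, the metallothionein gene MT1B, the auxin-conjugating enzyme gene GH3-8, the kinesin gene KIN14F and TF1 completed the 12, with log2 differences of 2.89, 2.87, 2.85, 2.85 and 2.75. KIN14F read 7.61 in green leaves, below the pseudocount, and its difference ran from 1.56 to 4.67 over the settings.

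At the low end, the glutaredoxin gene GRXC1 had a signal of 1059 in yellow leaf tips and 9190 in green leaves (log2 difference -3.04, and -3.11 to -2.97 over the settings). ACS1, an ACC synthase of ethylene production, had 14.8 against 309 (-3.10), but 14.8 is below the pseudocount, and its difference ran from -4.33 to -1.90. The aquaporin genes PIP2-5 and TIP2-2 differed by -2.21 and -2.03, the latter on a probe set that may cross-hybridize. The glutelin gene GLUB-4, also below the pseudocount in yellow leaf tips, differed by -2.17 (-3.01 to -1.26 over the settings), and 3 genes of diterpenoid or brassinosteroid metabolism, CYP99A2, KSL5 and CYP734A4, by -2.16, -1.91 and -2.05. Among bright genes, the copper transporter COPT1 had 3177 against 12820 (-1.95), the nicotianamine synthase NAS3 3115 against 12025 (-1.89), and the metallothionein gene MT2C 9688 against 35844 (-1.87, on 5 probe sets within 0.47 of each other). LOL4 differed by -1.85. For 13 of these 24 genes the lower signal lay within the range of the bacterial control probe sets of that array, so their exact sizes and order are uncertain. Among genes without a name, LOC4324081 had 10575 against 419 (4.64), and LOC9269452 had 643 against 11863 (-4.11), a lower value than any named gene.

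**Figure D2:**
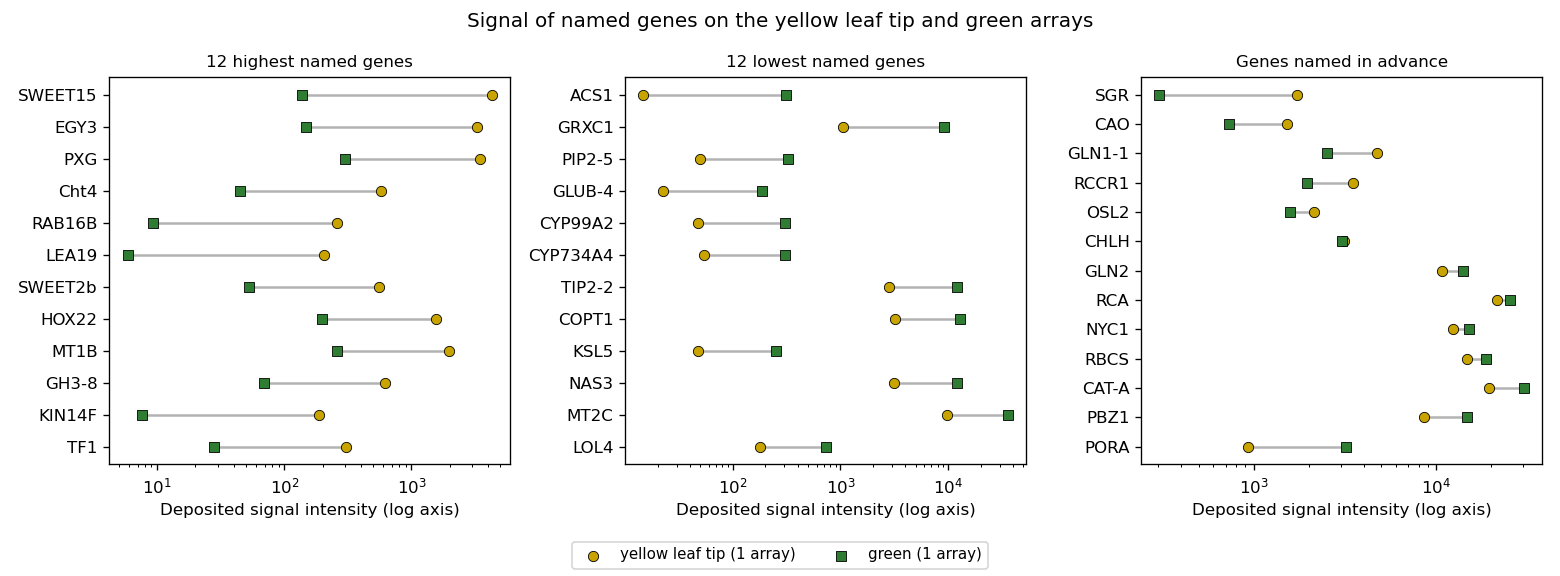
Deposited signal intensity (log axis) on the yellow leaf tip array (circles) and the green array (squares), 1 array each, for the 12 highest and 12 lowest named genes and for the 13 measured genes chosen in advance; a gene with several probe sets is drawn at their mean. SWEET15 lies at 4291 against 139, ACS1 at 14.8 against 309, and among the genes chosen in advance SGR (1725 against 304) and PORA (932 against 3188) lie furthest apart.

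Among chlorophyll breakdown genes, SGR stood apart: its signal was 1725 in yellow leaf tips and 304 in green leaves, 5.56-fold higher, and its 2 probe sets differed by 0.02. The other 3 measured members were within 2-fold. RCCR1, which acts late in the pathway, had a log2 difference of 0.88, NYC1, a chlorophyll b reductase, -0.24, and its partner NOL -0.15. The median of the list was 0.37, at the 89.2th percentile of random lists of like signal. Of the 16 chlorophyll synthesis genes, 12 had a difference below 0, and 1 was lower by at least 2-fold. That gene was PORA, a protochlorophyllide oxidoreductase, with 932 against 3188 (-1.70), and next came GSA at -0.63. PORB, another gene for this enzyme and named after its value was seen, had 7296 against 7432 (0.02), on a probe set that may cross-hybridize. CHLI had 0.22 and CHLH of the magnesium chelatase had 0.09. The gene listed as CAO, the name of the enzyme that makes chlorophyll b, was higher (1.08), but the gene table also lists it as Lls1, a name used for pheophorbide a oxygenase of chlorophyll breakdown, so its place is not settled. Counted as a breakdown gene, a choice made after seeing the data, it moved the breakdown median to 0.88 (99.8th percentile) and the synthesis median to -0.27 (1.44th percentile). The median of the synthesis list, -0.26, lay at the 0.98th percentile, but inside the central 95% of random lists after quantile normalization, after loess and with the filter at the 75th percentile.

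All 7 measured genes of carbon fixation and photorespiration had lower signals in yellow leaf tips. By the mean of its 2 probe sets (-1.49 and -0.75), the glycine decarboxylase subunit gene GDCSH was lower by more than 2-fold (-1.12). Its mean signals, 12838 against 22525, lie less than 2-fold apart, and 4 of the other settings ended this only 2-fold call of the list. The glycolate oxidase genes GLO3 and GLO1 had -0.91 and -0.21. The Rubisco small subunit gene RBCS differed by -0.50, but its 4 probe sets disagreed by 1.15, and Rubisco activase, RCA, by -0.20. Another small subunit gene, RBCS-A, was below the filter, at 32.7 in yellow leaf tips and 8.45 in green leaves. Apart from RBCS and RCA, the measured members are genes of photorespiration. The list's median of -0.50 lay at the 0.46th percentile and outside the central 95% of random lists under all 9 other settings. Of 10 light-harvesting and photosystem genes, 9 were below 0 and none reached 2-fold. PSAH had -0.75, LFNR1 -0.42 and RCABP69, on a probe set that may cross-hybridize, -0.19, while PSAG had 0.51 on 2 probe sets that disagreed by 1.29. The median of -0.26 was at the 6.25th percentile, and after quantile normalization it was 0.015, so no direction can be given for this list; RCABP69 also turned above 0 after quantile normalization and loess.

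Senescence-associated genes were on the whole higher in yellow leaf tips, with a median of 0.49 at the 99.5th percentile and outside the central 95% under all 9 other settings. Of the 10 measured members, 3 were higher by at least 2-fold: malate synthase, MS (776 against 123, 2.51), isocitrate lyase, ICL (272 against 53.1, 2.01), both of the glyoxylate cycle, and the phospholipase D gene PLD2 (1.16), the last named after its value was seen. The green signal of ICL lay within the range of the bacterial controls, and its difference ran from 1.39 to 2.41 over the settings. OSL2 had 0.48 and the cytosolic glutamine synthetase gene GLN1-1 0.94. PPDK1 had -0.42, and GLN1-2, with 1302 against 2719, was lower by just under 2-fold. Autophagy and protein breakdown genes had a median of 0.10 (66.6th percentile), with 3 of 25 higher by at least 2-fold. Among the higher ones were EGY3 and the Clp family gene CLPD1 (4590 against 914, 2.35), while FTSH3 had -0.79 and EGY2 -0.41. After quantile normalization the median of this list was 0.26, at the 98.7th percentile.

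Nitrogen assimilation genes, which share GLN1-1 and GLN1-2 with the senescence list, had a median of 0.52 at the 99.9th percentile, with 4 of 17 higher by at least 2-fold. The nitrate uptake partner NAR2.2 had a log2 difference of 2.19 (1.31 to 2.99 over the settings, on a green signal of 23.6 within the bacterial controls). Nitrate reductase NIA1 had 3027 against 766, but a log2 difference of 0.74 when no filter was applied, while GLT2, a glutamate synthase gene, had -1.27 and plastid glutamine synthetase GLN2 had -0.10. With the filter at the 75th percentile the median of this list was -0.10, and without a filter it was 0.06, so its place depends on the dimmer members. Starch synthesis and amylase genes had 3 of 8 higher by at least 2-fold, with SS1 at 1.82 and DPE1 at 1.61, AGPS2 at -0.18 and SSII-1 at -0.62. Their median of 0.39 lay at the 96.3th percentile, was 1.11 and above all random lists with the filter at the 75th percentile, and was 0.12 at the 61.4th without a filter. After quantile normalization, after loess, with the larger pseudocount and with the brightest probe set per gene this list also lay above the central 95%. In the list of sugar transport and cleavage, SWEET15 and SWEET2b were high while the sucrose transporter SUT1 (-1.26) and sucrose synthase SUS6 (-1.11) were low, and the median of 0.10 lay at the 51.1th percentile. SUS6 had 0.21 when no filter was applied and a further probe set entered.

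Abscisic acid and dehydration genes split. Of the 23 measured, 10 were below 0, and 7 were higher by at least 2-fold, RAB16B (3.19) and LEA19 (3.05) among them with the limits given above, and 1, the abscisic acid hydroxylase gene ABA8OX1, was lower (-1.06). Emp1 had -0.85. The median was 0.09 at the 56.7th percentile. The protein phosphatases 2C, some of which act in abscisic acid signalling, had 5 of 51 members higher, among them PP2C68 (2.16) and PP2C51 (2.09, on a green signal below the pseudocount), none lower, and a median of 0.05 (24.9th percentile), which was below 0 without centring. NAC transcription factors had a median of 0.41 (93.8th percentile), with NAC45 at 1.22, NAC067 at 0.93 and NAC068 at -0.20.

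The 4 defence lists had low medians, although of their 30 measured genes 5 were lower by at least 2-fold and 3 higher. Pathogenesis-related proteins had a median of -0.34 at the 1.58th percentile, but a mean of 0.30, with 2 of 10 members higher by at least 2-fold and none lower. PBZ1, a pathogenesis-related protein 10 gene, had 8564 against 14697 (-0.73) and chitinase LOC4348631 had -0.76, whereas Cht4 (3.21) and Cht1 (1.72) were high. The phytoalexin list had the lowest median, -0.75 at the 0.12th percentile: 2 of 9 genes, CYP99A2 and KSL5, were lower by at least 2-fold, KSL7 had 0.57 and CYP76M6 was higher (2.13, but 1.20 to 2.70 over the settings, on a green signal of 36.3 within the bacterial controls). Most of its members have locus numbers close together, from LOC4329722 to LOC4329730 or from LOC4335091 to LOC4335096. They may not vary independently, as the genes of the random lists do, so this percentile may look too extreme. The 6 WRKY factors matched by symbol had a median of -0.47 (1.17th percentile), with WRKY62 at -1.17, WRKY71 at -0.81, WRKY51 at 0.19 and WRKY9 at 0.56. Among 5 chitin and pattern receptor genes, LYP4 (-1.39) and the chitin receptor gene CEBIP (-1.27) were low and both genes listed as CERK1 had 0.12 and 0.15. The median of -0.53 lay at the 1.90th percentile. The phytoalexin list fell inside the central 95% without a filter and with the filter at the 75th percentile, the WRKY and receptor lists with the latter, and the pathogenesis-related list without a filter. The receptor list also fell inside, at the 2.84th percentile, among random lists drawn from named genes.

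Hormone lists differed from each other. Auxin response genes had a median of -0.30 at the 0.22th percentile, outside the central 95% under all 9 other settings, with IAA31 (-1.09, and -1.25 to -0.79 over the settings) and IAA3 (-1.04, and -0.43 without a filter) low and the auxin-conjugating genes GH3-8 (2.85) and GH3.2 (1.13) high. Ethylene genes had a median of -0.09 (16.9th percentile), and the lower members were ACS1 and the ACC oxidase gene ACO1 (-1.47), while the receptor gene ERS2 had 0.71. Jasmonate genes had a median of 0.22 (92.2th percentile), with OPR5 at 1.80 (0.61 without a filter, and on a green signal of 60.4 within the bacterial controls), JAMYB at 1.22 and JAZ9 at -1.21. Salicylate and phenylpropanoid genes had 0.19 (86.9th percentile), with CAD2 at 1.32 and NH4 at 1.17. NH3 had -0.66 on 4 probe sets that disagreed by 1.24. Cytokinin response regulators had a median of 0.05 (33.8th percentile), which was below 0 in all 3 other scalings.

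Iron homeostasis genes had a median of -0.33 at the 0.50th percentile, led by NAS3 and the vacuolar iron transporter gene VIT1.2 (2598 against 7420, -1.46), and no member was higher by 2-fold. Without a filter this median lay at the 14.8th percentile. Metallothioneins held both MT1B (2.87) and MT2C (-1.87), with a median of 0.15 (73.6th percentile). Of the antioxidant enzymes, 3 of 21 were higher, including the cytosolic superoxide dismutase gene SODCC.2 (15245 against 3203, 2.29) and APX7 (1.41), and the catalase gene CAT-A had -0.61. Glutathione S-transferases (median 0.29, 88.9th percentile), heat shock proteins (0.17, 81.5th) and heat shock factors (-0.02, 25.7th) lay within the central 95%, and the last turned sign after quantile normalization and loess.

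Of 24 cytosolic ribosomal protein genes, 21 were above 0 and none reached 2-fold, with RPL9 at 0.65, on a probe set that may cross-hybridize, and RPL18 at -0.80. Their median of 0.19 lay at the 98.5th percentile, and inside the central 95% without a filter and without probe sets that may cross-hybridize. The markers of other tissues did not point one way. All 8 seed storage and anther genes were below 0 (median -0.58, 0.94th percentile, and inside the central 95% without a filter), aquaporins had -0.19 (5.35th percentile, and 0.26th without a filter) with PIP1-3 high at 1.99, secondary wall genes had 0.38 (94.6th percentile) with LAC10 at 1.32, and wax and cutin genes had 0.04 (45.0th percentile), which was below 0 without centring. Several of the seed storage and anther genes were dim in yellow leaf tips, GLUB-4 at 22.3 among them, so a difference in background between the arrays could contribute to their sign. No member of the circadian clock list reached 2-fold: PRR37 had -0.70, PRR73 -0.53 and CCA1 0.16, and the median of -0.25 lay at the 6.96th percentile.

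Single 2-fold calls did not all hold. Of 79 named genes past the threshold and compared across the settings, 26 had their lower signal within the bacterial controls of that array, and 18 dropped below 2-fold in at least 1 setting fixed in advance. The 26 were, among the higher genes, Cht4, CYP76M6, EXPB2, GH3-8, ICL, KIN14F, LEA19, LTP-2, MADS4, NAR2.2, OPR5, PP2C51, RAB16B, SWEET2b and TF1. Among the lower ones they were ACS1, CYP734A4, CYP99A2, GLUB-4, Hd3a, HSFA2A, KIN10B, KSL5, LYP4, PIP2-5 and WRKY62, so the sizes printed for all these are uncertain. With the larger pseudocount KIN10B had -0.97, LYP4 -0.84, Hd3a -0.83, WRKY62 -0.73 and MADS4 0.69. The same setting took CEBIP to -0.98, NAC45 to 0.97, GH3.2 to 0.94 and NH4 to 0.87. Without a filter KIN14K had -0.77 and HSFA2A -0.31, and after loess the gene listed as CAO had 0.99. The others were GDCSH, NIA1, OPR5, IAA3, IAA31 and SUS6, with the values given above, and 42 of the 79 had neither limit.

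In all, 3 of 39 lists lay above the central 95% of their random lists and 9 below it. By chance 1.95 lists would lie outside if the genes within a list varied independently, as in the random lists. Related genes may vary together, so the excess over 1.95 is no measure of significance. The lists of carbon fixation and photorespiration, of senescence-associated genes and of auxin response were the 3 that stayed outside under every other setting fixed in advance. Most members of the first are photorespiration genes. The auxin response list was not a planned topic but among the 10 symbol families added after the annotation was seen.

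**Figure D3:**
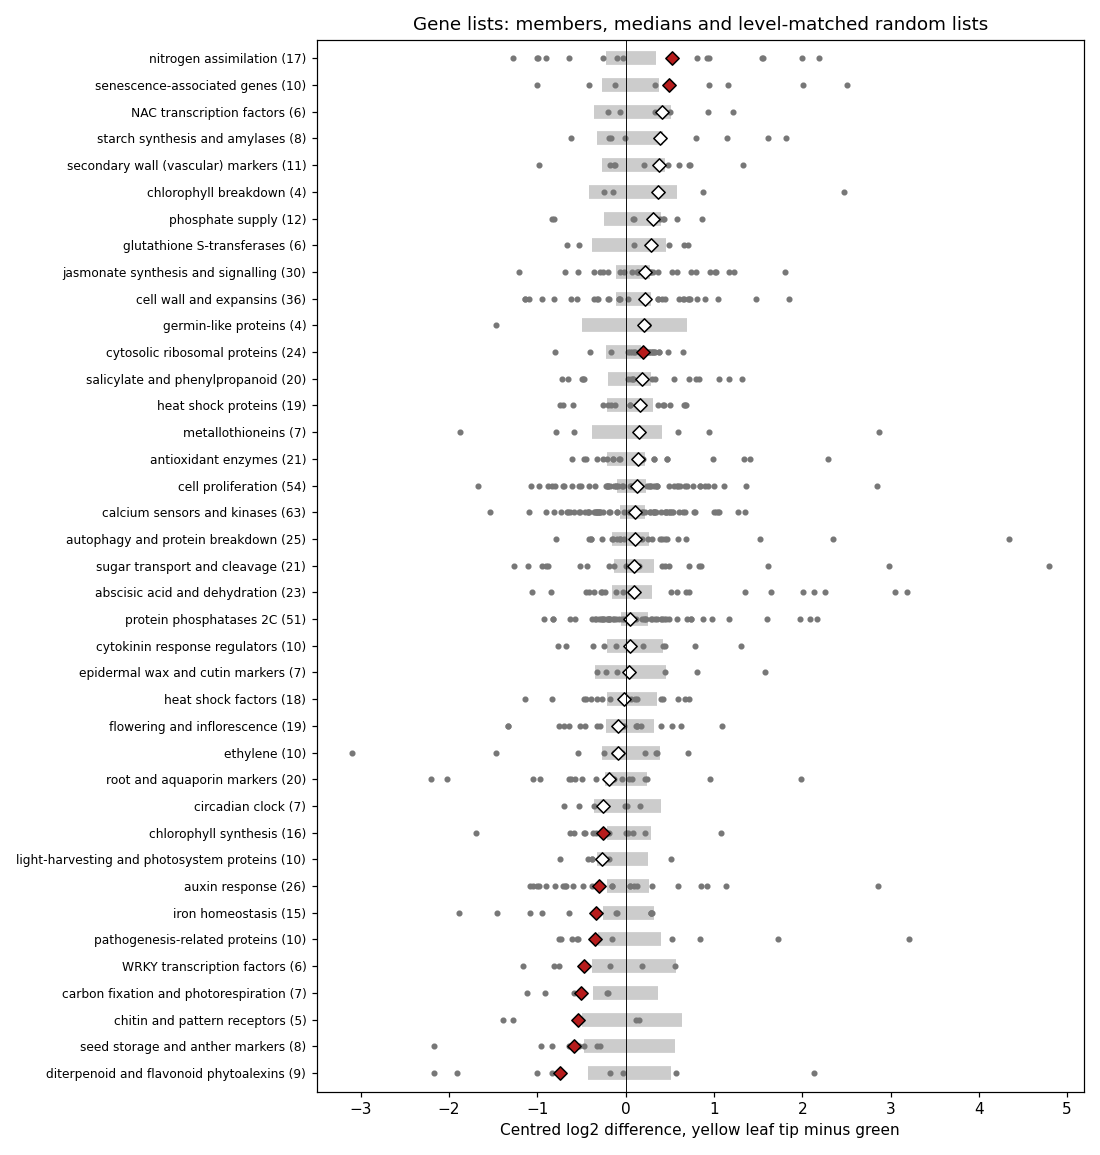
Centred log2 difference (yellow leaf tip minus green) of the members of 39 gene lists (grey points, 1 per measured gene, number in brackets), their median (diamonds) and the central 95% of medians of 10000 random lists of like signal (grey bars); red diamonds lie outside the bar. Nitrogen assimilation and senescence-associated genes have the highest medians (0.52 and 0.49) and the phytoalexin list the lowest (-0.75).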

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

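The array carries 10 control probe sets whose names begin with Mgr, taken here to stand for the rice blast fungus Magnaporthe grisea, which the comparison of rice genes did not use. One of them, for the middle of an elongation factor transcript (ef1a), stood out because its signal was above that of the green array and above the highest of 42 bacterial control probe sets on the same array. It read 81.6 in yellow leaf tips and 22.5 in green leaves, and the highest bacterial control in yellow leaf tips read 56.9. The probe set for the 5' end of the same transcript read 12.4 in yellow leaf tips and 64.2 in green leaves, and the 2 for its 3' end read 54.0 and 34.0 in yellow leaf tips and 14.2 and 19.0 in green leaves. The highest signal of the 10 was on the green array, 186 for the 3' end of a Gapdh transcript, against 75.9 in yellow leaf tips. The highest bacterial control on the green array read 97.6. No explanation was tested for these values.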

How the results depend on the processing

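No paired analysis was possible because each group had 1 array, and for the same reason no array could be left out. The counts of higher and lower probe sets were 312 and 261 at a size threshold of 2, 5330 and 5476 without a filter, 582 and 433 with the filter at the 75th percentile, and 1099 and 863 with the larger pseudocount. Without OsAffx probe sets, a choice made after seeing the data, 911 were lower. After loess 1934 were higher and 1323 lower, after quantile normalization 1821 and 1531, and without centring 1515 and 2021. The number of lists outside the central 95% was 12, it was 7 without a filter, and it ran from 8 to 13 elsewhere. The light-harvesting median moved from -0.26 to 0.015 after quantile normalization and -0.043 after loess. The cause was not tested, though both level the difference along signal and these genes are bright. With the filter at the 75th percentile the spread between probe sets was 0.30, the nitrogen assimilation median turned to -0.10 and the receptor median to 0.017, and 11 of the 24 highest and lowest named genes remained above the filter and past the threshold, since fewer genes enter. SUS6 turned to 0.21 without a filter. The other medians of the lists on chlorophyll, on carbon fixation and photorespiration, and on senescence kept their sign under each setting fixed in advance. Of 1447 comparisons of single named genes with an alternative, 1389 moved by less than the spread between probe sets, 57 moved by more and 1, SUS6, turned from past the threshold; the sign differed in 11 in all, the others from smaller values. Of 355 such comparisons of list medians, 322 moved by less than 1 SD of random lists, 31 by more, and 2 turned from outside the central 95%; the sign differed in 23 in all. Counting the gene listed as CAO among breakdown genes, a choice made after seeing the data, moved the chlorophyll breakdown median to 0.88. Without probe sets that may cross-hybridize LEA19, TIP2-2, RCABP69, RPL9, KIN14K and CIPK11 have no value, and the seed storage list has none with the filter at the 75th percentile. Signal over background limits the dim genes: the 42 bacterial controls reached 97.6 on the green array, above the filter of 86.0.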

Other observations

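The list medians and percentiles in this part were fixed in advance in their method. The tests of explanations were chosen after the values they measure were seen, except that of probe sets of other design in the dimmest 20%.

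Several gene families stood outside the themes described so far. Calcium sensors and kinases had 6 of 63 members higher by at least 2-fold and 2 lower, with CIPK2 at 1.35, CIPK11 at 1.27 on a probe set that may cross-hybridize, CML29 at -1.54 (3098 against 9345) and CIPK5 at -1.09, around a median of 0.11 (66.1th percentile). Cell proliferation genes had 4 of 54 higher, among them KIN14F (2.85) and the histone gene H2B.10 (1.36), and 2 lower, KIN10B (-1.67) and KIN14K (-1.07, on probe sets that may cross-hybridize). Cell wall and expansin genes had 3 higher and 3 lower of 36, with CSLE1 at 1.85, EXPB2 at 1.48 (1.06 to 1.72 over the settings, on a green signal of 77.8 within the bacterial controls), and CSLC1 and EXLA1 both at -1.14. Of the flowering genes (median -0.08, 15.9th percentile, but 2.02th with the filter at the 75th percentile, and a median of 0.13 without a filter), Hd3a and DTH8 were both at -1.33 and MADS4 at 1.09. Hd3a and MADS4 had their lower signals, 48.0 and 54.5, within the bacterial controls, and ran from -1.70 to -0.83 and from 0.69 to 1.54 over the settings. Phosphate supply genes had 10 of 12 members above 0 with PHT1-8 at 0.87 (median 0.32, 92.7th percentile), and the germin-like gene GER5 had -1.47 against a list median of 0.20 (65.7th percentile) and a list mean of -0.20.

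SGR, the glyoxylate cycle genes MS and ICL and 7 of 23 abscisic acid and dehydration genes, RAB16B among them, were higher in yellow leaf tips, while 10 of the 23 were below 0 and that list lay at the 56.7th percentile. The ratio of 3' to 5' signal differed between the arrays by at most 0.169 on the log2 scale among the actin, cyclophilin and Gapdh controls. For these transcripts that argues against a large difference in RNA degradation between the arrays. The bound on this ratio was set after the value was seen. The clock genes cannot settle whether the samples were taken at different times of day. Their largest difference was 0.695 in size, below the bound of 1, but that bound was set after the value was seen. PRR37 (-0.70) and PRR73 (-0.53, on 2 probe sets that differed by 0.04) were low, while CCA1 had 0.16. A shift of a short time would not show. The 11 higher members of the lists on chlorophyll breakdown, senescence, and abscisic acid and dehydration fell into 10 neighbourhoods more than 100 genes apart. This cannot decide on differences in cis within chromosome segments, since 1 segment may span more than 100 genes and the lines may differ in many segments. Open and untested are a senescence programme in the yellowing tips, water loss in drying tips, other differences between the lines, and a difference in the part or age of leaf sampled.

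The yellowing could resemble an infection response, in which pathogenesis-related genes would be high. The median of that list, known before this test was chosen, lay at the 1.58th percentile of random lists. Without a filter it lay at the 4.93th, so signals were not high across the measured list. Its mean was 0.30, however, Cht4 and Cht1 were high, and no member was lower by 2-fold. Most of the 10 measured members are chitinases, 6 further genes were below the filter, and PR1a and PR1b were not analysed here, so a response of single genes or of unmeasured ones stays open.

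Probe sets whose names begin with OsAffx had 889 lower calls against 410 higher, while the others had 911 lower against 1255 higher. After loess the ratio of lower to higher among OsAffx probe sets was 1.04, which loess brings about in part by construction, so this first test was set aside. Among the others the ratio after loess was 0.545, so a gap between the designs remained. A property of this design at every signal level is argued against by the brightest 20% of kept probe sets, where the ratio of lower to higher was 0.186 (8 against 43). A higher background on the green array may contribute: the 42 bacterial control probe sets had a median centred difference of -0.294, with 29 below 0, but the 10 Mgr controls had -0.09, with 6 below 0 and a higher median signal in yellow leaf tips (23.3 against 19.4), so this stays open. Low signal by itself stays undecided, since among probe sets of other design in the dimmest 20% the ratio was 1.14 (369 against 324), between the bounds set for and against it, while OsAffx probe sets there had 645 against 200. No biological explanation was tested for this pattern.

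Along the chromosomes, calls of higher genes were slightly more clustered than in shuffled gene orders. The variance-to-mean ratio over 730 windows of 20 neighbouring array genes was 1.05, at the 98.3th percentile of 1000 shuffles, and no window held more than 5 of the 819. For lower genes the ratio was 0.94 (25.8th percentile). This clustering was the first test tried for chromosome segments, and it lay by a small margin on the side they would give. The test cannot decide, since related neighbouring genes may vary together and the shuffles do not keep them together. It covers all higher genes rather than those of the 3 lists, and was replaced by the count of 10 neighbourhoods after its result was seen. That count cannot decide either, so differences in cis within chromosome segments stay open.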
